A study of Danio rerio with 24 samples.

How the data were processed

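The samples were jaws of AB zebrafish larvae, dissected after a 1 h exposure to TCDD at 1 ng/ml or to the vehicle, 0.1% DMSO, that began at 96 h post fertilization (hpf). Jaws were taken 1, 2, 4 and 12 h after the start of exposure, and each of the 24 arrays was hybridized with biotin-labelled RNA from a pool of 10 jaws, so that each of the 8 groups held 3 arrays. Per the labels' protocols, heads were severed in front of the pectoral fin and the eyes and brain were removed with forceps. The design text speaks of 3 independent replicate time courses, so the spread between arrays holds differences between pools as well as technical ones. It does not say whether the replicate number in a label marks the experiment.

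The deposited values were probe-set intensities on a linear scale, with array medians from 13.9 to 35 and a highest value of 32037. Per the submitters' processing notes, RMA and GCRMA were used, and their versions, order and roles were not given in the sources used here. RMA and GCRMA both correct background, normalize arrays to one another and summarize the probes of a probe set. The distribution of the deposited intensities was nearly the same among the 6 arrays of a time point and differed between time points. Medians were 22.1 to 24.1 at 1 h, 33.4 to 34.9 at 2 h, 25.9 to 27.9 at 4 h and 13.9 to 15.1 at 12 h. The time points therefore appear to have been normalized separately. Levels set across time points carry that difference, and contrasts of TCDD with vehicle within a time point do not. No detection calls came with the values, and the number of arrays limits the precision.

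The file held 15617 probe sets, of which 115 were controls and were left out. Through the platform annotation, 10795 probe sets had 1 gene symbol, 135 had several and 4572 had none; 10711 were matched by Entrez identifier to a table of current symbols, which changed 1 symbol. The 10795 named probe sets stood for 8793 symbols. Probe sets with several symbols or none were tested and are not named as genes. No probe set was annotated to cyp1b1. No reference genome was used here, so no coordinates are given.

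Values were analysed as log2(value + 1), and a fold change is on that scale, which understates the change of dim probe sets. A probe set was kept if it lay above the median of its array in at least 3 of the 24 arrays, which left 9157 probe sets and, with the probe set of highest mean value taken for each gene, 5906 genes. Of 687 tested genes with several probe sets, 2, 2, 3 and 19 had a called one at 1, 2, 4 and 12 h, and in 2 of the 19 the probe sets differed in sign. Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a constant prior), two-sided, over all 24 arrays in 8 groups, so that all contrasts shared 1 estimate of the spread with 16 residual degrees of freedom. Contrasts were TCDD against vehicle at each time, their average over the 4 times, and an F test of the 3 differences of the TCDD effect from that at 1 h. Others were the single difference of 12 h minus 1 h, and vehicle at 2, 4 and 12 h against vehicle at 1 h. P-values were adjusted by Benjamini and Hochberg within each contrast, and a probe set was called at an adjusted p under 0.05. Every adjusted p printed for a gene is from this test.

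Genes are named by a rule: for each TCDD contrast, the 10 largest rises and 10 largest falls among called probe sets with 1 symbol whose 3 TCDD arrays all lay above, or all below, the 3 vehicle arrays (for the average, with the 4 time contrasts of the same sign). For each vehicle contrast the 6 largest rises and falls were named. Also named were up to 4 members of each gene list with the smallest p, or 6 where the list was called, and cyp1a, cyp1b1, cyp1c1, ahr2, sox9a, sox9b, col2a1a, runx2b and ihha where measured. Any other gene named was chosen after its values were seen. Chance alone separates 3 arrays from 3 in 10% of cases (a share of 0.1).

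Gene lists were written from general knowledge: AHR pathway and xenobiotic metabolism (12 measured genes), oxidative stress response (19), cartilage (16), bone and perichondrium (25), hedgehog pathway (10), pharyngeal arch patterning and neural crest (33), FGF, BMP, TGF-beta and Wnt signalling (30), DNA replication and cell division (52), p53 and cell cycle arrest or death (19). Further lists were immediate early and stress genes (28), circadian clock and light regulated (17), cholesterol and lipid synthesis (10), and, as markers of other cell types that a dissected jaw can carry, skeletal muscle (29), heart muscle (6), skin and oral epithelium (29), blood and endothelium (5), immune and acute inflammation (13), nervous system (22), eye (11), and liver and gut (8). Pigment cells, with 4 measured genes, were not tested because a list needed 5. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 tested lists and the 4 TCDD contrasts, and apart from these over the lists and the average, the vehicle contrasts and the difference of 12 h minus 1 h. Camera with a correlation estimated for each list, and fry, which tests whether a list moves one way without comparing it with other genes, were run beside it. The number of members called is given over all probe sets and adjusted over the list alone.

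The sample groups, tests, gene lists, rule for named genes and most alternative settings were fixed before the data were examined; log2 of the value plus the pseudocount of 1 was the test planned in case the values were linear. Alternatives were the replicate number as a block, no filter, a stricter filter (above the 75th percentile of the array), an intensity trend with a robust prior, quantile normalization of the 24 arrays, median centring, a pseudocount of 16, and a required fold of 1.5. Further alternatives were an adjusted p under 0.01, a fit of only the 6 arrays of a time point, each array left out in turn, each time left out in turn, and gene-level means of probe sets. Leaving out both of a pair of arrays that stood apart from their groups, median centring of the vehicle contrasts, and the stricter filter for the vehicle contrasts, the average and the F test were chosen after seeing the data. A split of the DNA replication and cell division list into DNA synthesis and mitosis genes was also chosen after seeing the data.

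The scripts were tested on simulated data made from the fitted means and spread of the 9157 probe sets, with 200 probe sets changed at 12 h. Of 100 changes of 1 on the log2 scale 82% were recovered, and of 100 changes of 2, 95%; 187 probe sets were called, 10 of them not changed. Of 20 simulated lists, the 1 that was raised was called and 0 of the others were. Values were drawn independently for each probe set, so these lists held no correlation between genes. How the list test behaves under such correlation was not tried by this simulation.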

Results

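Expression was measured in the dissected jaws of zebrafish larvae exposed for 1 h to TCDD, a persistent dioxin that binds the aryl hydrocarbon receptor (AHR), or to the vehicle. The 24 arrays fell into 8 groups of 3: TCDD and vehicle at 1, 2, 4 and 12 h after the start of exposure, when larvae were 97, 98, 100 and 108 hpf. The series' title puts the question: how AHR activation acts on sox9b, which encodes a transcription factor of cartilage formation, during the malformation of the jaw. Replicates of a group correlated with Spearman coefficients of 0.923 to 0.979 across probe sets, and 0 pairs of arrays within a group held identical values. Pairs from different groups were not compared in this way. Changes are log2 fold changes of TCDD over vehicle with the standard error (SE) of the limma fit, and levels are mean log2(value + 1) ± SD of 3 arrays. For every gene said to have risen or fallen at a single time with TCDD, the 3 TCDD arrays lay all above or all below the 3 vehicle arrays. For bcor at 1 and 2 h, abcb5 and eomesa at 2 h, gins2 and mpx at 4 h, and mpx, tiparp, nt5c2l1 and cebpa at 12 h the mean of the lower group lay under the array medians. These are not clearly above background, so the sizes of these changes are uncertain. A pair of arrays stood apart from their groups: the log2 ratio of 3' to 5' signal of the gapdh control was 3.60 in TCDD 1 h replicate 2, against 1.06 and 1.60 in the other TCDD arrays and 1.45 to 1.85 in vehicle. In TCDD 12 h replicate 3 it was 0.97, against 3.11 and 3.70, and 3.28 to 3.85 in vehicle. The ratio of the acta1 control did not set these arrays apart (7.40 and 10.02). By that control TCDD 4 h replicate 3 was high, at 9.33, against 7.73 and 6.37 in the other TCDD arrays and 7.29 to 7.48 in vehicle.

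At 1 h, when exposure had just ended, cyp1a, the standard AHR-induced monooxygenase, and its relative cyp1c1 were already higher in TCDD larvae, by 1.87 (SE 0.30, adjusted p = 0.00449) and 2.05 (SE 0.28, adjusted p = 0.00124), or 3.65-fold and 4.14-fold. The level of cyp1a was 13.11 ± 0.12 (SD, n = 3) with TCDD and 11.24 ± 0.36 with vehicle. In the limma test 21 probe sets were called, 18 higher and 3 lower with TCDD, and they stood for 16 named genes. sox9b was not called (-0.35, adjusted p = 0.415; 6.83 ± 0.40 against 7.18 ± 0.10), nor was ahr2, the receptor that mediates TCDD effects in zebrafish (0.13, adjusted p = 0.848).

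The other genes that rose at 1 h included tiparp, an ADP-ribosyltransferase that represses AHR (1.99, SE 0.38, adjusted p = 0.025), and cyb5a, an electron donor of monooxygenases (1.90, SE 0.22, adjusted p = 0.000355). bcor, a transcriptional corepressor (2.00), pik3r3b, a regulatory subunit of PI3-kinase (1.76), the glycosyltransferase gene b3gnt3.1 (1.66) and the kinase gene nuak2 (1.39) rose with adjusted p of 0.000724, 0.000823, 0.00449 and 0.0411. The sulfotransferase gene sult6b1 rose by 1.12 (adjusted p = 0.00449). edn1, the endothelin that patterns the ventral pharyngeal arches, rose by 1.14 (adjusted p = 0.0117). Lower were f13a1b, which encodes a chain of clotting factor XIII (-1.31, adjusted p = 0.0305), and ca5a, a mitochondrial carbonic anhydrase (-0.95, adjusted p = 0.00449). edn1, f13a1b, nuak2 and tiparp each lost their 1 h call without some array.

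Of 12 measured genes of the AHR pathway, 3 were called higher at 1 h over all probe sets and 3 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.149). Cartilage genes were called lower as a list (median -0.39, 12 of 16 negative, camera adjusted p = 0.000524; adjusted p = 0.383 with an estimated correlation), with 0 members called over all probe sets or over the list alone by limma. Examples were hapln1a, a matrix link protein (-1.54), matn1 (-0.75), col9a3 (-0.67) and col2a1a, the main cartilage collagen (-0.40, adjusted p = 0.313). hapln1a had an SD of 1.46 with TCDD and 0.30 with vehicle, and a probe set of col11a2 read 3.27 in TCDD 1 h replicate 2, the array with the high gapdh ratio, against a mean of 6.12 in the other TCDD arrays. Without that array the list was still called, with a mean of -0.247 in place of -0.35. The bone and perichondrium list was called lower (median -0.03, mean -0.11, camera adjusted p = 0.0125; adjusted p = 0.535 with an estimated correlation), with 1 of 25 members lower when adjusted over the list alone. Its members included mef2ca (-0.87), phex (-0.75) and runx2b (-0.10), which lay under the array medians with TCDD and vehicle. The call was lost without TCDD 1 h replicate 2 or replicate 3 (mean over settings -0.234 to -0.00331). FGF, BMP, TGF-beta and Wnt signalling genes were called lower (median -0.06, camera adjusted p = 0.00421; adjusted p = 0.535 with an estimated correlation); fgfr3 stood at -1.03 and spry4 at -0.77. This call too was lost without TCDD 1 h replicate 2 (mean over settings -0.323 to -0.00238). Arch patterning and neural crest genes were not called as a list (adjusted p = 0.0785), with 1 member called over all probe sets (edn1) and 4 adjusted over the list alone, among them dlx4b (1.01) and prrx1a (0.96).

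The DNA replication and cell division list was called higher at 1 h, with a median of 0.41 and 47 of 52 members positive (camera adjusted p = 4.79e-06; adjusted p = 0.535 with an estimated correlation), 0 members called over all probe sets and 13 adjusted over the list alone. Examples were the mitotic genes birc5a (0.97), ccna2 (0.95), ccnb1 (0.94), aurka (0.92) and kif23 (0.85). Immediate early and stress genes were called lower (median -0.33, camera adjusted p = 0.000337; adjusted p = 0.535 with an estimated correlation), 3 of 28 adjusted over the list alone. Their examples atf3 (-1.59) and egr1 (-1.39) had vehicle SDs of 1.2 and 1.18, and the call was lost without vehicle 1 h replicate 1. Clock and light-regulated genes were called lower (median -0.32, 14 of 17 negative, camera adjusted p = 2.89e-05; adjusted p = 0.0982 with an estimated correlation), with cry1b at -1.05 and 2 members lower adjusted over the list alone. Skeletal muscle genes were called lower (median -0.30, 25 of 29 negative, camera adjusted p = 3.54e-06; adjusted p = 0.535 with an estimated correlation). Relative to the vehicle mean, these genes averaged -0.93 in TCDD 1 h replicate 2, the array with the high gapdh ratio, and 0.12 and -0.24 in the other TCDD arrays.

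The remaining lists were not called at 1 h. The adjusted p was 0.131 for oxidative stress, 0.958 for hedgehog, 0.0645 for p53, 0.568 for cholesterol synthesis, 0.441 for heart, 0.108 for skin, 0.521 for blood and endothelium and 0.825 for the nervous system. The liver and gut list (0.503) had a median of -0.58 and a mean of 0.27. The immune list (0.418) had a median of 0.04 and a mean of 0.05 against a test directed downward. Eye genes (0.188) had a median of 0.74, with 3 of 11 higher adjusted over the list alone, and their mean stood 1.74 above vehicle in TCDD 1 h replicate 1.

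The count at 1 h rests on the pooled spread and on single arrays. With only the 6 arrays of that time in the limma fit 0 probe sets were called (1075 at an unadjusted p under 0.05); without TCDD 1 h replicate 3 251 were called, 176 of them higher, and without vehicle 1 h replicate 3 35. Without TCDD 1 h replicate 2 the split was 21 higher and 1 lower, and after quantile normalization of the 24 arrays 17 higher and 10 lower.

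At 2 h, tiparp, cyp1c1, cyb5a and cyp1a remained higher, and the chemokine receptor gene cxcr4b was higher as well. tiparp rose by 2.48 (SE 0.38, adjusted p = 0.0039; 5.57-fold), cyp1c1 by 2.01 (SE 0.28, adjusted p = 0.00154), cyb5a by 1.81 (SE 0.22, adjusted p = 0.000722) and cyp1a by 1.55 (SE 0.30, adjusted p = 0.0247; 13.78 ± 0.09 against 12.23 ± 0.30). cxcr4b rose by 1.33 (SE 0.17, adjusted p = 0.000722; 2.52-fold). Calls numbered 19, of which 15 were higher and 4 lower, and they stood for 17 named genes. Of the probe sets called higher, 11 were shared with 1 h, where 0.029 would be shared were calls independent (Fisher's exact test, p = 4.58e-29). They are not, since all contrasts shared 1 estimate of the spread, so the expected number and p are only a guide.

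Also higher at 2 h were edn1 (1.41, adjusted p = 0.00154), bcor (1.39), pik3r3b (1.30), sult6b1 (1.29, adjusted p = 0.00154) and cxxc5a, a zinc finger gene (1.2, adjusted p = 0.0066). ccn2a, connective tissue growth factor, rose by 1.05 (SE 0.19, adjusted p = 0.0166), and myog, a regulator of muscle differentiation, by 1.09 (SE 0.22, adjusted p = 0.0397). Lower were the transporter gene abcb5 (-1.63, adjusted p = 0.0247), the T-box gene eomesa (-1.57, adjusted p = 0.032), the proliferation gene mycn (-0.91, adjusted p = 0.0472) and the protocadherin gene pcdh18a (-0.79, adjusted p = 0.0133). sox9b stood at -0.54 (adjusted p = 0.629; 6.24 ± 0.23 against 6.78 ± 0.12), ahr2 at 0.66 with the same adjusted p, and col2a1a at -0.55.

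The AHR list was called higher at 2 h (median 0.36, camera adjusted p = 3.56e-05; adjusted p = 0.0982 with an estimated correlation), with 3 of 12 members called over all probe sets and 4 adjusted over the list alone. Oxidative stress genes were called higher (15 of 19 positive, camera adjusted p = 0.0289; adjusted p = 0.535 with an estimated correlation), with gpx1a at 0.48. The p53 list was called higher as well (adjusted p = 0.0458; adjusted p = 0.535 with an estimated correlation), with foxo3b at 0.55. Cartilage genes were again called lower (median -0.25, 14 of 16 negative, camera adjusted p = 0.00939; adjusted p = 0.535 with an estimated correlation), and 0 members were called by limma. The DNA replication list was called lower (median -0.06, mean -0.13, camera adjusted p = 0.0406; adjusted p = 0.861 with an estimated correlation), with ccnd1, the G1 cyclin, at -0.88 and mcm3 at -0.58. Nervous system genes were called lower (adjusted p = 0.0437; adjusted p = 0.715 with an estimated correlation), with syt1a at -0.63 and elavl3 at -0.62.

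Muscle, immune, and liver and gut lists were called higher at 2 h. For skeletal muscle the median was 0.23 with 27 of 29 positive and myog the 1 called member (camera adjusted p = 1.84e-05; adjusted p = 0.567 with an estimated correlation). For immune genes the median was 0.13 with cxcr4b the 1 called member (adjusted p = 0.0266; adjusted p = 0.383 with an estimated correlation), and lyz stood at 0.96. Liver and gut genes had a median of 1.33, all 8 positive (camera adjusted p = 0.000243; adjusted p = 0.535 with an estimated correlation), with 0 called over all probe sets and 1 adjusted over the list alone. Their mean stood 3.2 above vehicle in TCDD 2 h replicate 3 and 1.14 above in replicate 1, and 1.36 above the vehicle mean in vehicle 2 h replicate 1. Lists not called at 2 h were bone (0.418), hedgehog (0.279), arch patterning (0.568), FGF, BMP, TGF-beta and Wnt signalling (0.568, with 2 members higher and 2 lower adjusted over the list alone), immediate early genes (0.942), clock (0.0984), cholesterol synthesis (0.958), heart (0.948), skin (0.855), blood (0.568) and eye (0.958). Of the lists called at 2 h, only AHR kept its call with each array left out. With only the 6 arrays of this time 6 probe sets were called. Without vehicle 2 h replicate 1 13 were called, 0 of them lower. Of the genes named, abcb5, eomesa, mycn, pcdh18a, bcor, ccn2a, myog and pik3r3b each lost their call without some array. The call of cyp1a at 2 h was lost with each array but vehicle 2 h replicate 1 left out (adjusted p over all settings 0.009 to 0.175).

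At 4 h, sox9b was lower and cyp1a and ahr2 were higher in TCDD larvae. sox9b fell by 2.33 (SE 0.20, adjusted p = 5.18e-07), from 8.01 ± 0.17 to 5.68 ± 0.34, or 5.01-fold. Another, dim probe set of sox9b read 2.41 to 2.59 in all 8 groups and did not pass the filter. cyp1a rose by 3.77 (SE 0.30, adjusted p = 3.75e-07), from 10.08 ± 0.70 to 13.85 ± 0.12, or 13.7-fold, and ahr2 rose 2.33-fold (1.22, SE 0.25, adjusted p = 0.016). Calls numbered 68, of which 48 were higher and 20 lower, and they stood for 51 named genes.

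The AHR list was called higher at 4 h (camera adjusted p = 2.89e-05; adjusted p = 0.0982 with an estimated correlation), with a median of 0.12 and a mean of 0.80. Its 4 called members of 12 were cyp1a, ahr2, cyp1c1 (2.81, adjusted p = 5.56e-06) and tiparp (2.78, adjusted p = 0.000399). cyb5a rose by 2.68 (SE 0.22, adjusted p = 4.96e-07; 6.43-fold). The chemokine receptor gene cxcr4b rose by 2.01 (SE 0.17, adjusted p = 5.18e-07; 4.03-fold), and the chemokine gene ccl27a by 2.76 (SE 0.40, adjusted p = 0.000681). A probe set annotated to mpx, neutrophil myeloperoxidase, rose by 3.42 (SE 0.50, adjusted p = 0.000681); it tracked cyp1a across the contrasts, and the 3 other mpx probe sets were dim and flat, and which transcript it reads is in doubt. The immune list was called higher (median 0.21, 10 of 13 positive, camera adjusted p = 0.00274; adjusted p = 0.147 with an estimated correlation), with cxcr4b and the mpx probe set its 2 called members. The chaperone genes hsp70.3 (2.87, SE 0.29, adjusted p = 5.56e-06; 7.31-fold) and dnajb1b (1.54, adjusted p = 0.00398) rose, while the immediate early and stress list was not called (0.533).

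Genes of DNA replication and cell division were called lower at 4 h (median -0.44, 42 of 52 negative, camera adjusted p = 2.34e-18; adjusted p = 0.147 with an estimated correlation), 9 members over all probe sets and 24 adjusted over the list alone. Among them were cdca7a (-1.51, adjusted p = 0.00147), mcm2, mcm3 and mcm5 of the replicative helicase (-1.42, -1.12 and -1.13; adjusted p = 0.0209, 0.00556 and 0.0157), and gins2 (-1.22, adjusted p = 0.00279). Also called were the maintenance methyltransferase gene dnmt1 (-1.25, adjusted p = 0.0173) and orc6 of the origin recognition complex (-1.10, adjusted p = 0.0201). Outside the list, mcmbp, a partner of the helicase (-1.19, adjusted p = 0.00398), and the mitotic kinesin gene kif20a (-1.96, adjusted p = 0.0186) were lower. When the list was split after seeing the data, all 31 DNA synthesis genes were negative (median -0.71; unadjusted p = 0.000927 with an estimated correlation), and the 16 mitosis genes had a median of 0.06 (unadjusted p = 0.816 with an estimated correlation).

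**Figure D1:**
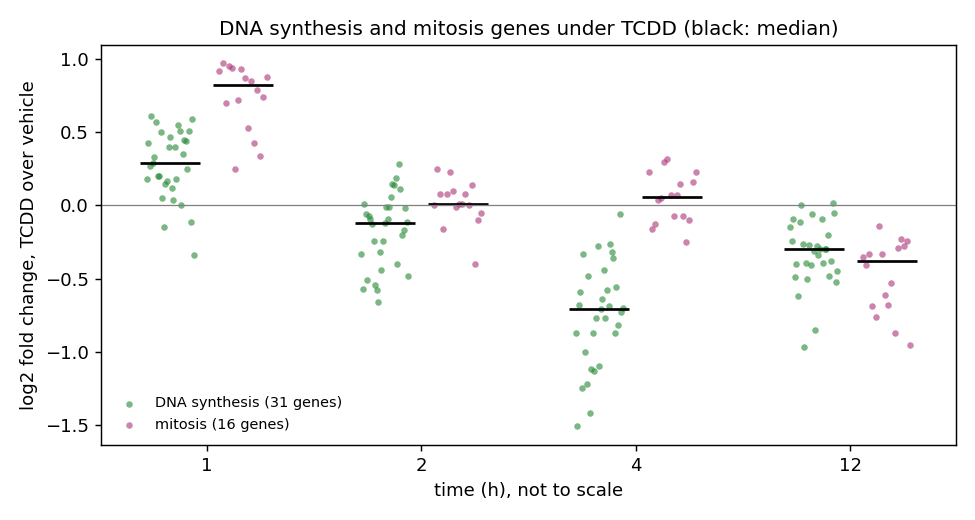
Log2 fold change of TCDD over vehicle (vertical axis) of the 31 DNA synthesis genes and the 16 mitosis genes at 1, 2, 4 and 12 h, 1 point per gene, with a black bar at the median. The DNA synthesis medians were 0.29, -0.12, -0.71 and -0.30 and the mitosis medians 0.82, 0.01, 0.06 and -0.38.

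Signalling and patterning genes were also among the calls at 4 h. edn1 rose by 1.48 (adjusted p = 0.000386) and lhx8a, a homeobox gene of the jaw, by 1.03 (SE 0.16, adjusted p = 0.00147), the 2 called members of the arch list, which itself was not called (0.503; median -0.06, mean 0.09). FGF, BMP, TGF-beta and Wnt signalling genes were called higher (adjusted p = 0.0317; adjusted p = 0.701 with an estimated correlation), with il17rd, an FGF antagonist (0.96, adjusted p = 0.00602), and ccn2a (0.94, adjusted p = 0.0157) called and 3 adjusted over the list alone. The p53 list was called higher (0.0462; adjusted p = 0.535 with an estimated correlation), with the transcription factor gene foxo3b called (0.90, SE 0.14, adjusted p = 0.00179). Lower were the endothelial gene plvapb (-1.42, adjusted p = 0.00279), the matrix gene spon2b (-1.39, adjusted p = 0.00602) and the peroxiredoxin gene prdx1 (-1.27, adjusted p = 0.0112), whose brighter probe set read -0.94 and was not called (adjusted p = 0.17).

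Cartilage genes other than sox9b were not called at 4 h. The list had a median of 0.08, a mean of -0.06 and an adjusted p of 0.872, col2a1a stood at 0.10 (adjusted p = 0.993) and runx2b, of the bone list (0.568), at -0.02. runx2b read 4.03 with vehicle and 4.02 with TCDD, under the array medians, so its lack of change says little. Nervous system genes were called lower (median -0.37, 19 of 22 negative, camera adjusted p = 0.000594; adjusted p = 0.535 with an estimated correlation), with 0 members called by limma; gad1b stood at -0.93 and snap25b at -0.76. The nervous system, FGF and p53 list calls at 4 h were lost without some array. Not called were oxidative stress (0.395, with 1 member higher and 3 lower adjusted over the list alone), hedgehog (0.231), clock (0.418), cholesterol synthesis (0.609), muscle (0.533), heart (0.418), skin (0.537), blood (0.616), eye (0.604) and liver and gut (0.955). Without TCDD 4 h replicate 1 37 probe sets were called and without vehicle 4 h replicate 1 45, and with only the 6 arrays of this time 10. ccn2a, dnmt1, il17rd, kif20a, mcm2, mcm5, orc6, prdx1 and spon2b each lost their 4 h call without some array. The call of ahr2 at 4 h was lost without TCDD 4 h replicate 1 or 2 or vehicle 4 h replicate 1 (adjusted p over all settings 0.00339 to 0.439).

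At 12 h, cyp1a stood 498-fold higher in TCDD larvae and sox9b 12.9-fold lower. cyp1a rose by 8.96 (SE 0.30, adjusted p = 2.52e-14), with 13.65 ± 0.17 in TCDD larvae and 4.69 ± 0.66 in vehicle. sox9b fell by 3.69 (SE 0.20, adjusted p = 1.4e-10), from 7.71 ± 0.16 to 4.03 ± 0.30, and ahr2 rose by 1.91 (SE 0.25, adjusted p = 0.000156), from 5.99 ± 0.17 to 7.91 ± 0.27. The sox9b level with TCDD lay near the array medians (lowest 3.89), so the exact size of its fall is uncertain. Calls numbered 137, of which 69 were higher and 68 lower, and they stood for 107 named genes. Of those called higher at 4 h, 21 were higher again at 12 h (0.36 expected by chance, Fisher's exact test, p = 1.75e-33). Among those lower, 4 were shared (0.15 expected, Fisher's exact test, p = 1.23e-05), namely sox9b, ccnd1, plvapb and spon2b. As at 2 h, these expected numbers and p are only a guide.

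**Figure D2:**
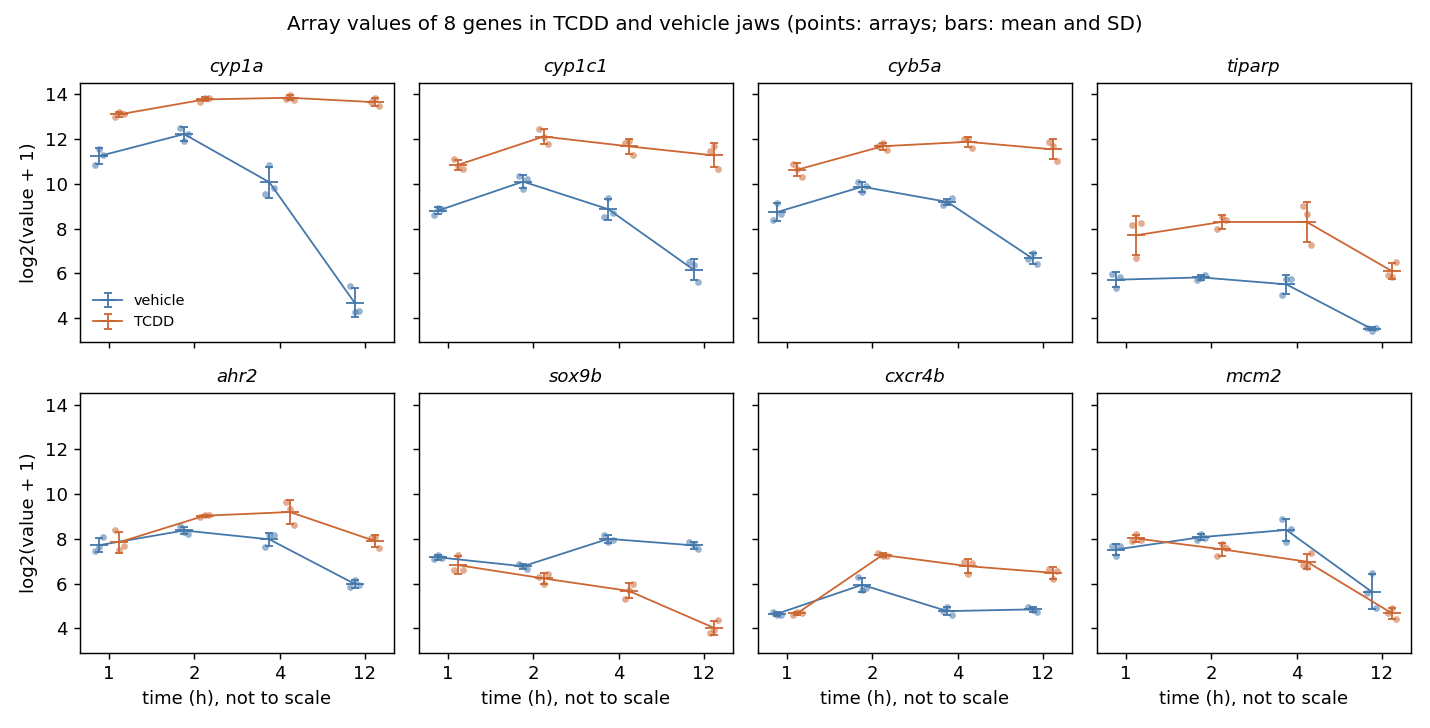
Level of 8 genes as log2(value + 1) (vertical axis) in vehicle and TCDD jaws at 1, 2, 4 and 12 h (horizontal axis, not to scale); points are arrays, with the mean and SD of 3. In TCDD jaws cyp1a lay between 13.11 and 13.85 at all times while in vehicle it was 4.69 at 12 h, and sox9b in TCDD jaws was 6.83, 6.24, 5.68 and 4.03. Levels across times carry the apparent separate scaling of the time points.

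The AHR list was called higher at 12 h (median 0.57, mean 1.71, 10 of 12 positive, camera adjusted p = 3.26e-11). Of the 27 list calls over the 4 times this was the 1 that passed adjustment with an estimated correlation (adjusted p = 0.00912). Its members called were cyp1a, ahr2, cyp1c1 (5.11, adjusted p = 1.44e-10; 34.5-fold), tiparp (2.58, adjusted p = 0.000628) and the glutathione transferase gene gstp1.2 (0.83, adjusted p = 0.00787). When adjusted over the list alone 6 were called, and nqo1 stood at 0.64 (adjusted p = 0.133). cyb5a rose 29.4-fold (4.88, SE 0.22, adjusted p = 6.88e-12) and sult6b1 9.14-fold (3.19, adjusted p = 1.44e-10). Other large rises were ccl27a (3.46, adjusted p = 3.27e-05), jac1 (3.29, SE 0.49, adjusted p = 0.000628), and nt5c2l1, a nucleotidase-like gene (1.74, adjusted p = 0.000416). The probe set annotated to mpx rose by 5.58 (SE 0.50, adjusted p = 5.8e-07) from 2.99 ± 0.01 in vehicle, with the doubt given for 4 h. That vehicle level lies among the means of the dim mpx probe sets (2.67, 2.84 and 3.04), so the rise is a lower bound. gclm, of glutathione synthesis, rose by 0.81 (adjusted p = 0.00654), the 1 called member of the oxidative stress list, of which 3 passed adjusted over the list alone and which was not called (0.0647).

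At 12 h the chemokine receptor gene cxcr4b rose by 1.63 (adjusted p = 6.95e-06), and its ligand gene cxcl12a fell by 1.5 (SE 0.18, adjusted p = 5.63e-05). The immune list, which holds both, was called higher (median 0.23, camera adjusted p = 0.0347; adjusted p = 0.383 with an estimated correlation), with 2 members higher, of which 1 is the doubted mpx probe set, and 1 lower. The other 12 members had a median of 0.19 (SE 0.26). The immune, hedgehog and muscle list calls at 12 h were each lost without some array. Among signalling genes, ccn2a (1.22, adjusted p = 0.00111), il17rd (0.83, adjusted p = 0.0167) and edn1 (0.85, adjusted p = 0.0354) rose. axin2, a feedback gene of Wnt signalling (-0.86, adjusted p = 0.0474), fell, and the FGF, BMP, TGF-beta and Wnt list was not called (0.279). The hedgehog list was called lower (median -0.17, 8 of 10 negative, adjusted p = 0.0437; adjusted p = 0.535 with an estimated correlation), with the hedgehog inhibitor gene hhip called (-0.81, adjusted p = 0.0264) and 2 adjusted over the list alone. foxd3, of the neural crest, fell by 1.15 (adjusted p = 0.0139), and the arch list was not called (0.82; median -0.03, mean 0.04).

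Skeletal genes were represented at 12 h by a few falls beside sox9b. col5a2a (-0.98, adjusted p = 0.00227), col10a1a, a collagen of hypertrophic cartilage and bone (-0.81, adjusted p = 0.0308), and col1a2 (-0.66, adjusted p = 0.047) were lower. These were 3 of the 25 bone and perichondrium genes, of which 1 was higher and 4 lower adjusted over the list alone. That list was not called (0.385; median 0.05, mean -0.03), nor was the cartilage list (0.435; median -0.04), in which sox9b was the 1 called member; col2a1a stood at -0.01 (adjusted p = 1) and runx2b at -0.32. sox9a and ihha were dim at all times, sox9a between 2.30 and 2.86, and did not pass the filter. Other falls were the keratin genes krt94 (-1.92, adjusted p = 0.000483) and krt15 (-1.86, SE 0.38, adjusted p = 0.0139), and f13a1b (-1.74, adjusted p = 0.00179). Lower too were anxa2a, an annexin (-1.5, SE 0.16, adjusted p = 1.12e-05), the differentiation factor gene cebpa (-1.39, adjusted p = 0.0131), limch1b (-1.40, adjusted p = 0.00489) and myoc (-1.34, adjusted p = 0.00269).

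The DNA replication and cell division list was called lower at 12 h too (median -0.33, 49 of 52 negative, camera adjusted p = 1.59e-10; adjusted p = 0.383 with an estimated correlation). Called were ccnd1 (-0.91, adjusted p = 0.0239), the polymerase clamp gene pcna (-0.85, adjusted p = 0.0355) and kif23, of cytokinesis (-0.87, adjusted p = 0.0418), and 7 adjusted over the list alone. cdkn1bb, which encodes the cyclin-dependent kinase inhibitor p27, rose by 0.84 (adjusted p = 0.014), the 1 called member of the p53 list (0.642). hsp90aa1.2 rose by 1.52 (adjusted p = 0.00654) in the stress list (0.616), and tefa, a clock-controlled transcription factor gene, by 1.26 (adjusted p = 0.00268) in the clock list (0.995). Skeletal muscle genes were called lower (median -0.17, 22 of 29 negative, camera adjusted p = 0.00164; adjusted p = 0.715 with an estimated correlation), with aldoab, a glycolytic aldolase, called (-1.29, adjusted p = 0.0017). Not called were cholesterol synthesis (0.503), heart (0.206), skin (0.695, with 3 members lower adjusted over the list alone), blood (0.568), nervous system (0.178), eye (0.392, 0 of 11 positive) and liver and gut (0.825). Of the pigment cell genes, too few for a list test, paics fell by 0.59 (adjusted p = 0.0395).

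Without TCDD 12 h replicate 3, the array with the low gapdh ratio, 67 probe sets were called at 12 h, and without vehicle 12 h replicates 1, 2 and 3 the counts were 71, 85 and 89. With only the 6 arrays of this time 21 were called, and without both arrays that stood apart, a setting chosen after seeing the data, 84. Of the 40 genes named as called at 12 h, 25 kept their call with each array left out in turn, cyp1a, sox9b and ahr2 among them. axin2, ccnd1, cebpa, col10a1a, col1a2, edn1, foxd3, gstp1.2, hhip, kif23, krt15 and pcna were among the 15 that did not.

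Averaged over the 4 times, which uses 12 arrays against 12, the TCDD effect was called in 175 probe sets, 107 higher and 68 lower. They stood for 129 named genes. cyp1a stood at 4.04 (SE 0.15, adjusted p = 1.95e-13; 16.4-fold), cyp1c1 at 3 (SE 0.14, adjusted p = 1.04e-11), cyb5a at 2.82 (SE 0.11, adjusted p = 4.13e-13), tiparp at 2.46 and sult6b1 at 1.76 (adjusted p = 2.88e-11). sox9b fell 3.31-fold (-1.73, SE 0.10, adjusted p = 2.9e-10), and ahr2 rose by 0.98 (adjusted p = 5e-05). Called on average at sizes near or under 1 were the arch gene prrx1a (0.58, adjusted p = 0.00424), the growth factor gene fgf10a (0.38, adjusted p = 0.00525), the cartilage gene hapln1a (-1.03, SE 0.25, adjusted p = 0.0322) and the Wnt antagonist gene dkk2 (-0.81, adjusted p = 0.00241). Others were hsd11b2, a steroid dehydrogenase (-0.91, adjusted p = 0.000532), the stromal gene cd248a (-0.80, adjusted p = 0.000444), jun (-0.55, adjusted p = 0.00853) and fgfr4 (-0.41, adjusted p = 0.00554). Of these 8 genes only cd248a kept its call with each replicate number left out. col2a1a (-0.21, adjusted p = 0.31) and runx2b (-0.11), which lay under the array medians at 1, 2 and 4 h, were not called. Without the 12 h arrays 67 probe sets were called on average and without the 2 h arrays 94, and with 1 replicate number left out 58, 73 and 85 (numbers 1, 2 and 3).

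In all, 8 probe sets were called at each of the 4 times, all of them higher. Of these 7 were named: cyp1a, cyp1c1, cyb5a, sult6b1, tiparp, edn1 and cxxc5a. Of these, tiparp and edn1 at 1 h, cyp1a at 2 h and edn1 at 12 h lost their call without some array. The calls of cxxc5a at 1, 4 and 12 h and of sult6b1 at 4 h were not followed with arrays left out. The effect differed between times in 16 probe sets, which stood for 13 named genes, by the F test of limma. From 1 h to 12 h the TCDD effect on cyp1a grew by 7.09 (SE 0.42, adjusted p = 1.96e-09), on cyp1c1 by 3.06 (SE 0.40, adjusted p = 0.000319), and on cyb5a by 2.98 (SE 0.31, adjusted p = 2.19e-05). That on ahr2 grew by 1.78 (SE 0.35, adjusted p = 0.0259). This test of 12 h against 1 h is separate from the F test, in which ahr2 (adjusted p = 0.0925) and kif23 (adjusted p = 0.0564) were not called. For sox9b that difference was -3.33 (SE 0.28, adjusted p = 8.14e-07), and for kif23 it was -1.72 (SE 0.30, adjusted p = 0.00983). tiparp was not called (0.59, SE 0.54, adjusted p = 0.699), with a difference limited by its low vehicle level at 12 h (3.53). In TCDD jaws the levels at 1 h and 12 h were 13.11 and 13.65 for cyp1a, 10.86 and 11.28 for cyp1c1, and 10.64 and 11.55 for cyb5a. In vehicle they were 11.24 and 4.69, 8.81 and 6.17, and 8.74 and 6.67. For ahr2 they were 7.85 and 7.91 with TCDD and 7.72 and 5.99 with vehicle. On the deposited values, whose scale differs between times, the larger effect on these genes thus lay mostly in lower vehicle levels. After quantile normalization the vehicle changes of cyp1a, cyp1c1, cyb5a and ahr2 were -5.60, -1.67, -1.11 and -0.79. For cyb5a and ahr2 that reading therefore rests on the deposited scaling. The count of the F test was 10 without the 1 h arrays, 30 without those at 4 h and 3 without those at 12 h, and 8, 8 and 7 with replicate numbers 1, 2 and 3 left out.

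Vehicle larvae themselves changed with time, and 4991 probe sets at 2 h, 1824 at 4 h and 6787 at 12 h were called against vehicle at 1 h. These counts carry the apparent separate scaling of the time points. The median of all probe sets moved by 0.53, 0.21 and -0.84 on the log2 scale, and 95.9%, 83.6% and 7.8% of the calls were higher. After quantile normalization of the 24 arrays the medians were -0.01, 0.01 and 0.03, and 1743 probe sets (815 higher, 928 lower), 1000 (487 higher, 513 lower) and 5134 (2643 higher, 2491 lower) were called. Quantile-normalized values, which stand relative to that shift, are given beside the deposited ones for part of the genes below. The log2 ratios of 3' to 5' signal in vehicle also differed between these times: 1.45 to 1.85 at 1 h and 3.28 to 3.85 at 12 h for gapdh, and 7.65 to 7.75 and 10.35 to 11.24 for acta1. The changes at 12 h are confounded with this difference.

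In vehicle larvae, the clock list was called lower at 12 h than at 1 h. Of 17 clock and light-regulated genes, 14 were called lower and 2 higher (median -3.05, camera adjusted p = 0.00309; adjusted p = 0.285 with an estimated correlation). Called lower were ciarta, a circadian repressor gene (-5.28, SE 0.15; -5 quantile-normalized), tefa (-5.16; -4.24) and nr1d2b, a REV-ERB nuclear receptor gene (-5.09; -4.95), while bmal2, of the activating arm, stood at 1.49 and nfil3-5 at 1.79. The AHR genes cyp1a (-6.55, SE 0.30; -5.60 quantile-normalized), cyp1c1 (-2.64; -1.67) and ahr2 (-1.73; -0.79) also fell. sox9b rose by 0.53 (adjusted p = 0.022; 1.52 quantile-normalized), a call lost without vehicle 1 h replicate 1 or 3 or vehicle 12 h replicate 1 (adjusted p over all settings 7.62e-06 to 0.0821). Also among the 6 largest falls at 12 h were the ribosomal protein gene rpl6 (-4.85; -3.77) and igf2bp3 (-4.72; -4.70), and among the 6 largest rises rgs5a (2.94, SE 0.62; 4.10), the cell cycle phosphatase gene cdc25b (2.72; 3.70) and tox (1.93; 2.81). Of those 6 rises, 5 (not tox), and rpl6, were among 67 probe sets that in both arrays that stood apart lay past the midpoint toward the other time.

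At 2 h the largest rises in vehicle were genes of the eye, which dissection removed: pde6ha, a cone phosphodiesterase (4.52, SE 0.76; 3.90 quantile-normalized), and opn1sw1, the ultraviolet cone opsin (3.77; 3.18 quantile-normalized, no longer called, as without some single array). All 11 measured eye genes were called higher (median 2.08), though the list was not called (camera adjusted p = 0.48). Falls included cyp24a1, which inactivates vitamin D (-2.11, SE 0.34; -2.18 quantile-normalized). At 4 h the oxidoreductase genes txnrd3 (3.03) and sqor (2.04, SE 0.25) were higher, and the stress-response genes fosab (-2.86), atf3 (-2.27) and xpc (-1.93, SE 0.12) lower. After quantile normalization this txnrd3 probe set read 2.74, while another probe set of the gene read 0.41 and was not called. The call of txnrd3 was lost without vehicle 4 h replicate 1, and that of fosab without any 1 of 4 arrays (values over all settings -3.73 to -1.31). sox9b was 0.82 higher at 4 h (adjusted p = 0.0076; 0.64 quantile-normalized, no longer called) and stood at -0.40 at 2 h, not called, or -0.98 and called when quantile-normalized. The count at 4 h was 921 without vehicle 4 h replicate 1, and 923 and 946 without vehicle 1 h replicates 1 and 2.

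**Figure D3:**
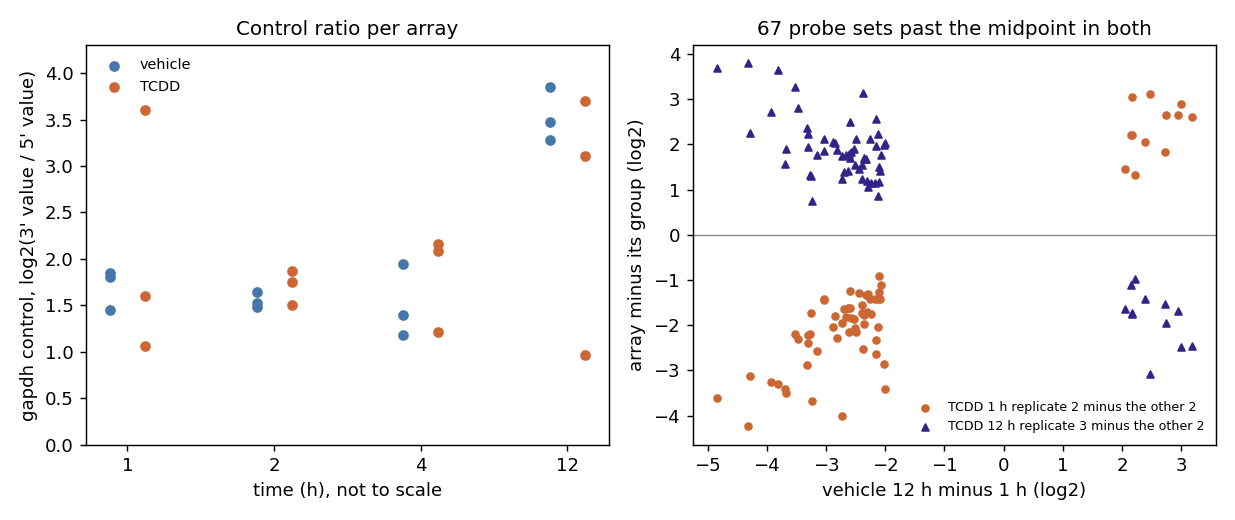
Left, log2 ratio of 3' to 5' signal of the gapdh control on each array by time (h). Right, the 67 probe sets past the midpoint in both arrays: horizontal axis, vehicle at 12 h minus 1 h (log2); vertical axis, the array minus the mean of the other arrays of its group (log2) for TCDD 1 h replicate 2 (circles) and TCDD 12 h replicate 3 (triangles), which lay on opposite sides.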

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

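The tests of separate normalization, time of day, neutrophils and a transcript induced like cyp1a were chosen only after the result was seen, as was the setting without both arrays that stood apart.

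The TCDD effect at 12 h differed from that at 1 h, by the limma test of the difference, for 29 probe sets, 15 higher and 14 lower. Of these, 13 belonged to genes that the rule had named for a TCDD contrast. Among genes of the AHR list the difference was 7.09 for cyp1a, 3.06 for cyp1c1 and 1.78 for ahr2, while tiparp was not called (0.59, adjusted p = 0.699). It was 2.98 for cyb5a, 2.07 for sult6b1, 3.44 for ccl27a, 4.01 for the probe set annotated to mpx, 1.60 for cxcr4b and 1.74 for nt5c2l1, and it was -3.33 for sox9b, -1.72 for kif23, -1.77 for bcor and -1.35 for anxa2a. On the deposited values, lower vehicle levels at 12 h made up most of the difference for cyp1a, cyp1c1, cyb5a and ahr2. After quantile normalization the vehicle changes of these genes were -5.60, -1.67, -1.11 and -0.79, so for cyb5a and ahr2 this rests on the deposited scaling. By the F test nt5c2l1 (adjusted p = 0.145) and bcor (adjusted p = 0.0611), like ahr2 and kif23, were not called. The vehicle level of the mpx probe set at 12 h (2.99) lay among the dim probe sets, so 4.01 is a lower bound. tiparp and nt5c2l1 were dim in vehicle at 12 h and bcor at 1 h, which limits how exactly their differences are known. The same holds for sox9b, whose TCDD level at 12 h lay near the array medians. For hsp70.3 the difference between 12 h and 1 h was 0.84 (adjusted p = 0.418), but the F test over the 4 times was called (adjusted p = 0.00056), with an effect of 2.87 at 4 h. Gene lists whose mean TCDD effect differed between these times, by camera with the preset correlation, were the AHR pathway (1.2), the immune list (0.52), immediate early and stress genes (0.41), oxidative stress (0.29), clock genes (0.27), FGF, BMP, TGF-beta and Wnt signalling (0.26) and DNA replication and cell division (-0.78). With an estimated correlation only the AHR list held (adjusted p = 0.0314), and the others had adjusted p of 0.285 to 0.738.

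TCDD 1 h replicate 2 and TCDD 12 h replicate 3 departed from their groups on the same probe sets in opposite directions. Exchanged labels are argued against by the clock genes, which in these arrays stood at no more than 0.13 of the way to the other time (20 probe sets). In these arrays, 67 of 871 probe sets lay past the midpoint toward the other time in both, against at most 4 for the other 8 pairs of arrays. That count restates the pattern, so a technical difference between the 1 h and 12 h arrays that both cross stays open. 54 of the 67 had a gene name, among them rpl6, rpl14, rps29 and eif4a1a. What differed in RNA or labelling stays open too, since the gapdh ratio followed the split and the acta1 ratio did not (7.40 and 10.02), and no biological explanation was tested.

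Of the 8 probe sets that TCDD raised at all 4 times, 7 were called lower in vehicle larvae at 12 h than at 1 h. Of all 9157 tested probe sets, 6256 were called lower there, and 2491 after quantile normalization, so the 7 alone say little. The 8 were also picked by contrasts that use these same vehicle arrays. Separate normalization as the whole cause is argued against by the 6 still called lower after quantile normalization of all arrays. After it cxxc5a stood at 0.06, and the probe set with no gene name rose by 0.80 (adjusted p = 0.00194). AHR activity in vehicle larvae that ebbs by 12 h is a possible explanation, but the other 40 probe sets raised by TCDD at 4 h had a median change of -0.10 (SE 0.24), at percentile 20.3 of 10000 matched random sets, which does not decide. Time of day or age stays open too: clock genes changed by a median of -2.81 over the same hours after quantile normalization, and the design ties time of day to age and to time after handling. RNA or labelling was not tested and stays open as well: in vehicle the log2 ratio of 3' to 5' signal was 1.45 to 1.85 at 1 h and 3.28 to 3.85 at 12 h for gapdh, and 7.65 to 7.75 and 10.35 to 11.24 for acta1. The 498-fold rise of cyp1a at 12 h is measured against this low vehicle level.

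The probe set annotated to mpx followed TCDD. More neutrophils in the TCDD jaws are argued against by the other 12 immune genes, whose median change at 12 h was 0.19 (SE 0.26, from -1.50 to 1.63), with lyz at 0.05, lcp1 at 0.16 and coro1a at 0.23. A transcript induced like cyp1a may be what this probe set reads: among all other tested probe sets its pattern over the 7 TCDD and vehicle contrasts ranked 1 in cosine with that of cyp1a (0.968, then ahr2 with 0.953). The 12 h contrasts in that pattern are limited by the dim vehicle level. The pattern also includes the rises at 4 h and 12 h themselves, and other genes raised by TCDD came close. The rank thus cannot tell mpx induced by TCDD from another transcript. The identifiers of all 4 mpx probe sets carry the cluster number of the cyp1a probe set, and the other 3 were dim and flat. Probe sequences were not used here.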

How the results depend on the processing

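Leaving out both arrays that stood apart, median centring of the vehicle contrasts and the stricter filter for the vehicle contrasts, the average and the F test were tests chosen only after the result was seen. No named gene changed the sign of a called TCDD effect under any setting run. Of the genes named as called, 15 of 40 at 12 h, 6 of 28 at 4 h (cxcr4b, cyb5a, cyp1a, cyp1c1, hsp70.3 and sox9b), 4 of 16 at 2 h, 0 of 12 at 1 h and 17 of 49 on average kept their call in all settings. With each array left out in turn 18 of 28 kept it at 4 h, 7 of 16 at 2 h and 8 of 12 at 1 h. At an adjusted p under 0.01 the counts were 11, 9, 36 and 51 at 1, 2, 4 and 12 h and 17 of the list tests, by construction. With only the 6 arrays of a time, which leaves fewer degrees of freedom, limma called 0 at 1 h (1075 at an unadjusted p under 0.05), 6 at 2 h, 10 at 4 h and 21 at 12 h. Leaving out 1 array gave 14 to 251 at 1 h (251 without TCDD 1 h replicate 3, 35 without vehicle 1 h replicate 3). It gave 37 to 66 at 4 h (37 without TCDD 4 h replicate 1, 45 without vehicle 4 h replicate 1) and 67 to 128 at 12 h (67 without TCDD 12 h replicate 3; 71, 85 and 89 without vehicle 12 h replicates 1, 2 and 3). Without both arrays that stood apart 84 were called at 12 h, of which 63 were among the 137. The average gave 58 to 85 without 1 replicate number (58, 73 and 85 for numbers 1, 2 and 3), 94 without the 2 h arrays and 67 without those of 12 h. The F test gave 7 to 8 without 1 replicate number, 10, 30 and 3 without the arrays of 1, 4 and 12 h, 25 with an intensity trend and robust prior and 26 with the stricter filter. Beyond the loss of arrays, the cause was not tested. Of the 27 list calls 1 held with an estimated correlation, and fry gave 7 list calls. In vehicle larvae quantile normalization gave 1743 and median centring 2210 at 2 h, and 1000 and 1144 at 4 h, where the shift of the median was removed. No filter gave 2898 at 4 h; the stricter filter, which tests fewer probe sets, gave 2704, 570 and 3947 at 2, 4 and 12 h. The count at 4 h ranged from 921 to 1860 (921 without vehicle 4 h replicate 1; 923 and 946 without vehicle 1 h replicates 1 and 2). sufu in vehicle at 12 h reversed, from -0.62 to 0.319 after quantile normalization, which took out the shift of -0.84. As arrays give no detection calls here, dim probe sets such as sox9a, ihha and the dim sox9b probe set cannot be told from background.

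With the replicate number as a replicate block, 26, 19, 68 and 130 probe sets were called at 1, 2, 4 and 12 h, 173 on average and 24 by the F test, and 5029, 1803 and 6806 in vehicle. The list tests then gave 25 list calls. Arrays with the same number in TCDD and vehicle correlated in their deviations at -0.47 to 0.23, with 2 of 12 pairs over 0.1 and 3 of 12 arrays nearest to their own number, so the numbers did not pair the arrays.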

Other observations

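The split of the cell division list into DNA synthesis and mitosis genes was chosen only after the result was seen; the tests by other splits of the arrays were not.

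The 31 DNA synthesis genes had median TCDD effects of 0.29, -0.12, -0.71 and -0.30 at 1, 2, 4 and 12 h, with p of 0.362, 0.334, 0.000927 and 0.101 from camera with an estimated correlation; 31 of 31 were negative at 4 h. The 16 mitosis genes had medians of 0.82, 0.01, 0.06 and -0.38, with p of 0.0415, 0.893, 0.816 and 0.0848; 16 of 16 were positive at 1 h and 16 of 16 negative at 12 h. The difference between the 2 sets was not tested, and none of these p was adjusted.

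cxcr4b was called at 2, 4 and 12 h (1.33, 2.01 and 1.63) and its ligand gene cxcl12a fell by 1.5 at 12 h, and on average by 0.67 (adjusted p = 0.000132), a call lost without the 12 h arrays. The heat shock gene hsp70.3 rose at 4 h (2.87), and hsp90aa1.2 at 12 h (1.52). Another probe set of cyp1c1 was called on average (2.89, SE 0.63, adjusted p = 0.015) and at no single time, with SDs among TCDD arrays of 2.5, 0.57, 2.74 and 2.81.

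Splits of the 6 arrays of a time into 3 and 3 number 10, so a share under 0.05 cannot be reached (smallest 0.1). The real split gave 21, 19, 68 and 137 calls at 1, 2, 4 and 12 h, and the highest other split 3, 1, 7 and 4, so that 1 split, the real one, reached the count each time. In vehicle at 2, 4 and 12 h against 1 h the real counts were 4991, 1824 and 6787 and the highest others 7, 3 and 0. Of 100 splits within the time points, 1, the real one, reached the 175 calls of the average (highest other 25). Chance is thus an unlikely source of that count, though 100 splits cannot exclude it. For the F test 2 of 100 splits reached the real count of 16, and the other gave 40. That split exchanged all 3 TCDD and 3 vehicle arrays of 4 h and left those of 12 h as they were, so it turned the TCDD effect at 4 h around against that at 12 h, which makes an effect of TCDD differ between times. For list calls with the preset correlation 1 of 100 reached 27. Other splits gave 6 to 26 (median 17), so a single list call of this kind is weak evidence of a TCDD effect. With an estimated correlation the real split gave 1 list call and the highest other split 3.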
